A study of Bos taurus with 12 samples.

How the data were processed

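RNA from bovine T cells was compared on 2-colour arrays, in which 2 RNA samples labelled with the dyes Cy3 and Cy5 compete for the same spots. Per the labels, cells were cultured for 6 days with leptospiral antigen, and proliferating CD4+ alphabeta and WC1+ gammadelta T cells were then isolated by flow cytometric sorting from 3 vaccinated animals. Per the labels, the reference was a pool of RNA from unstimulated, ex vivo blood mononuclear cells of 3 control animals. The 12 arrays fell into 4 sets of 3, 1 array per animal: CD4 (Cy3) with WC1 (Cy5), the dye swap WC1 (Cy3) with CD4 (Cy5), CD4 (Cy3) with reference (Cy5), and WC1 (Cy3) with reference (Cy5).

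The values were the deposited scores of the authors' value table, 1 per row and array, over 3888 rows. The unit is called a score here because the log base, the channel in the numerator, the background treatment and the normalisation are not given in the sources used here. Values of both signs with array medians near 0 have the shape of centred log ratios. However, 3 columns spread over 10 times as widely as the other 9, so the columns may not share 1 unit. No value is therefore given as a fold change. Spot intensities, background and scanner settings were not available, so signal over background is unknown, and for arrays the number of arrays limits the precision.

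Each array was centred on its median and divided by its median absolute deviation times 1.4826; an effect of 1 scaled unit is thus the robust standard deviation of the rows of an array. Effects keep the sign of the deposited values. That sign could not be tied to a direction of expression, because the lineage marker lists fixed for this purpose had 0 (CD4, gammadelta) or 1 (B cells, monocytes) listed members and the gene names were not borne out by the values. Each row was tested on its own. A row had to have a value on every array of a comparison.

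The comparisons and tests were set before the data were examined. They were CD4 with WC1 on the direct arrays, CD4 with the reference, WC1 with the reference, and CD4 with WC1 through the reference. In the direct comparison, the 2 swapped arrays of an animal were turned by their dyes and averaged, which gave n = 3 animals. The first 3 comparisons tested the mean of 3 animals against 0, and the last the difference between 3 and 3 arrays. All used limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with the Benjamini-Hochberg adjusted p threshold at 0.05. The mean of a group and its SD over animals are given with each effect. The limma p rests on a variance drawn towards that of all rows, so it does not follow from the SD beside it. Row 1102 of WC1 against the reference, for example, had an SD of 2.48 and a limma SE of 0.643. Correlations between the estimates were computed across rows, which are not independent replicates, so they carry no p-value; a jackknife over animals gives their standard error. Row structure was examined in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, with 95% intervals by Fisher's transformation for the check of names and from 1000 bootstrap draws of blocks of 54 rows for the comparisons across duplicate rows.

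Per the labels, equally numbered CD4 and WC1 samples came from the same animal. In the check of this pairing, the deviations of the CD4 and WC1 reference arrays from their group means correlated at 0.055, 0.0044 and 0.025 within animals 1, 2 and 3. The values between different animals follow from these by the centring on 3 arrays and add no separate evidence, so the pairing rests on the labels. Animal as a block was an alternative for the comparison through the reference.

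Several choices departed from the plan once the scores had been seen and before rows were counted. The plan was to use the values as deposited and to average rows of 1 gene symbol; centring with scaling, and rows kept apart, had been meant for comparison and became the standard. The intended variant with a minimum log ratio became at least 1 scaled unit. The planned list tests (camera) were not run, since 0 of the 26 fixed gene lists had 5 or more listed members. The platform annotation listed 1 gene symbol for 1458 rows, several symbols for 27, and none for 2403; 443 of the 444 single symbols were found by their Entrez number in the RefSeq gene table (assembly ARS-UCD2.0), with 0 symbols changed. The rule for named genes was, per comparison, the 10 highest and the 10 lowest named genes past the threshold with the same sign in 3 animals, or the 10 genes with the smallest p where fewer than 5 passed; up to 4 members of each list with at least 3 listed genes; and a fixed set of T cell and control genes. Because the listed names did not behave as names of these rows, the first part of the rule was replaced by row numbers, at most 2 per sign in each comparison. The lists covered gammadelta, CD4, CD8 and NK, B cell, myeloid, and platelet and granulocyte markers, MHC class I and II, cytotoxic effectors, type 1 and type 2 responses, T cell activation, receptor signalling, cytokine receptors, cytokines, chemokines, chemokine receptors and adhesion, cell cycle and its inhibitors, apoptosis, NF-kB and Toll-like receptors, immediate early genes, interferon-induced genes, metabolism, translation, and loading controls.

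The variants fixed beforehand were the values as deposited, centring without scaling, rows of 1 symbol averaged, each animal left out in turn, values for at least 2 of 3 animals, a robust prior, the minimum effect, a joint fit of 12 arrays with a dye term, single dye orientations, all 6 direct arrays with a dye term, rows with opposite signs in the 2 orientations left out, the dye effect of the direct arrays subtracted from the reference arrays, and the replicate block. Variants added after the data were seen were averaging of adjacent odd and even rows, removal of a running median over 81 rows from each array, and the swapped arrays taken as already turned by the authors. The first plan, the values as deposited with rows of 1 symbol averaged, became a variant at that point. The mean of both populations against the reference was also added then. Every variant with a dye effect or a dye term assumes that the deposited values keep the dye orientation.

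The procedure was tested on simulated data with 200 of 3874 rows changed, by 1, 2 or 4 scaled units. With 3 animals against the reference it recovered 55.2% of the rows changed by 2 units for CD4 and 79.1% for WC1, and 100% of those changed by 4 units in both. It recovered 98.5% of the rows changed by 2 units in the direct comparison, and 25.4% of them in the comparison through the reference. The unchanged rows called were 4, 8, 14 and 3 in number, respectively. The simulated noise was normal and independent between rows and arrays. It held no shared reference, dye effect, trend or row pairs, so these counts do not cover false calls from those sources. The 98.5% holds only if the swapped arrays keep the dye orientation, since the changes were added to values already turned by the dyes. On arrays turned by the authors, a CD4 and WC1 difference would cancel in the direct comparison. No array was left out.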

Results

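Gene expression of CD4+ alphabeta T cells and WC1+ gammadelta T cells, the bovine gammadelta subset that carries the WC1 surface receptor, was measured on 12 2-colour arrays of 3888 rows each. Both populations came from co-cultures of cells of 3 vaccinated animals and had proliferated in response to leptospiral antigen. The arrays comprised 3 direct comparisons of CD4 (Cy3) with WC1 (Cy5), 3 dye-swapped repeats of them, 3 comparisons of CD4 with a pooled unstimulated blood cell reference and 3 of WC1 with that reference. The table lacked 12 values on the CD4 reference array of animal 3 and 2 on the WC1 (Cy3) direct array of animal 3, and was complete elsewhere. The number of arrays limits the precision, since no spot intensities were available.

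The deposited values had array medians between -0.0054 and 0.0012. Their spread fell into separate ranges. On 3 direct arrays (both of animal 1, and CD4 in Cy3 of animal 2) the standard deviation over rows was 0.231 to 0.290. On the other 9 arrays it was 0.0147 to 0.0209. The median spread of the first set was 13.4 times that of the second. All effects below are in scaled units, in which every array has a median of 0 and a robust standard deviation of 1, and their sign is that of the deposited values, which does not say which RNA was the more abundant.

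**Figure D1:**
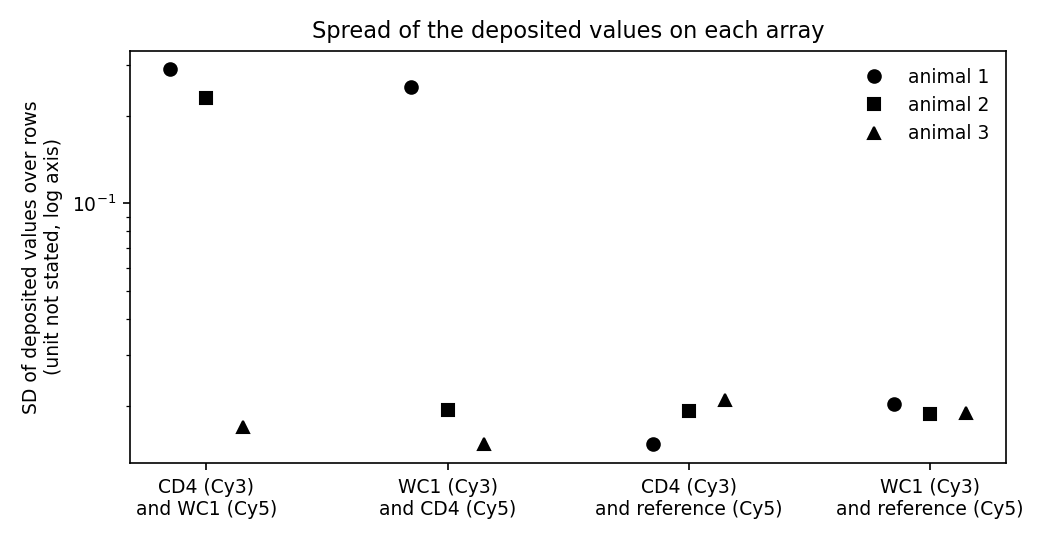
Standard deviation of the deposited values over rows (log axis, unit not stated) for each of the 12 arrays, by dye set; each point is 1 array and its symbol gives the animal. The 3 wide arrays lie between 0.231 and 0.290 and the other 9 between 0.0147 and 0.0209.

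Arrays of the same kind shared little of their variation across rows. Between animals, the mean Pearson correlation was 0.118 for CD4 with the reference (0.056 to 0.229), 0.139 for WC1 with the reference (0.120 to 0.157), 0.074 for the direct arrays with CD4 in Cy3 (0.044 to 0.107) and 0.127 for those with WC1 in Cy3 (0.116 to 0.143). The swapped arrays of an animal correlated at 0.044 on average (-0.021 to 0.098). A value that kept the dye orientation would be negatively correlated in a swapped pair, and one already turned by the authors positively correlated, so the orientation of the swapped arrays stayed unsettled.

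The rows were found to come in pairs. After removal of the trend along the rows, the mean of the 6 reference arrays correlated at 0.386 between an odd row and the even row that follows it, and at 0.081 between an even row and the odd row after that. The odd and even correlation was the higher of the pair of values on 12 of 12 arrays, at 0.078 to 0.278 against -0.032 to 0.074. On the CD4 reference array of animal 3 they were nearly equal. The pairing was looked for after the values had been seen, in a search over row distances. The rows of an odd and even pair are called duplicate rows or duplicate spots below, as a name only. That they are spots of the same sequence was not shown.

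**Figure D2:**
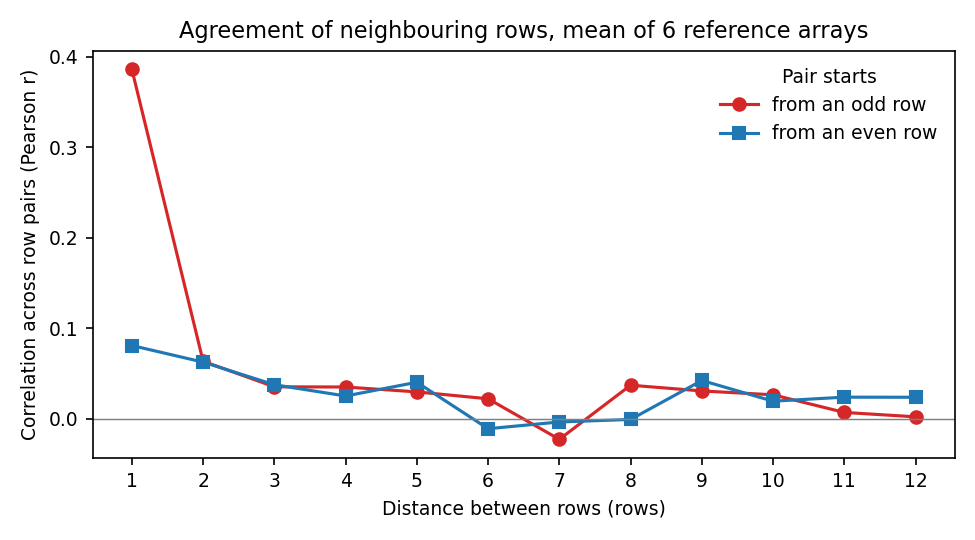
Pearson correlation across row pairs of the mean of the 6 reference arrays (trend removed), against the distance between the rows in rows; circles start from odd rows and squares from even rows. At a distance of 1 row the correlation is 0.386 from odd rows and 0.081 from even rows.

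The gene names of the platform annotation did not follow these pairs. The annotation lists 495 accessions on 3 consecutive rows each. Odd and even pairs correlated at 0.388 when listed under 1 accession (95% interval 0.310 to 0.460, 495 pairs) and at 0.460 when listed under different accessions (0.335 to 0.570, 174 pairs). Even and odd neighbours listed under 1 accession correlated at 0.048 (-0.040 to 0.136, 495 pairs), and rows of 1 accession lying 2 rows apart at 0.092 (0.0035 to 0.178, 495 pairs). As extremes chosen by their values, rows 1514 and 1515, the neighbours of 1 accession with the widest gap and both listed as ITGAL, averaged -1.24 ± 1.18 and 1.74 ± 0.38 over the 6 reference arrays (SD), whereas the odd and even rows 1815 and 1816, listed as ENDOD1 and BOLA-DMA, averaged 2.07 ± 0.44 and 2.21 ± 0.65. Rows are therefore given by their number in the value table.

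The direct arrays asked which genes differ between antigen-stimulated CD4 and WC1 cells of the same animal. With the swapped arrays turned by their dyes, 0 of 3886 rows passed the threshold by limma (smallest adjusted p 0.162), and 228 rows (5.87%) had an unadjusted p under 0.05, where 194.3 are expected by chance. Without scaling, 88 rows had it with the values as deposited and 94 with centring alone, both below the number expected by chance. The wide arrays then outweigh the narrow ones in the mean and spread over animals, so these counts neither bear out nor remove the excess. The estimates of different animals correlated at 0.038 on average (0.032 to 0.044). With the swapped arrays taken as already turned, 3 rows passed, all with positive values, 449 rows (11.6%) had an unadjusted p under 0.05, and the animals correlated at 0.155 on average (0.143 to 0.179). With adjacent odd and even rows averaged, 4 pairs passed when turned by the dyes, 1 of them positive, and 23 when taken as already turned, 11 of them positive.

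The CD4 arrays against the reference asked which genes differ between stimulated CD4 cells and unstimulated blood cells. By limma, 0 of 3876 rows passed the threshold (smallest adjusted p 0.138), and 345 rows (8.90%) had an unadjusted p under 0.05 against 193.8 expected by chance. The count depended on animal 3: without its array 65 rows passed, 41 positive and 24 negative. Of these, 57 had the same sign in their duplicate row, 44 in the array of animal 3 and 49 in the WC1 mean. The shares of such signs over all rows were not computed, and a pair with both rows called would enter as 2 rows. The array of animal 3 correlated at 0.056 and 0.070 with the CD4 arrays of animals 1 and 2, which correlated at 0.229 with each other. With odd and even rows averaged, 6 of 1932 pairs passed, 5 of them positive. The reference was a single pool always labelled with Cy5, so neither its own spread nor a dye effect is removed from these values.

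The WC1 arrays against the same reference asked the corresponding question for gammadelta cells. By limma, 11 of 3888 rows passed the threshold, 7 positive and 4 negative, and 394 rows (10.1%) had an unadjusted p under 0.05 against 194.4 expected by chance. The highest positive effects were those of row 1442, at 3.21 ± 1.12 scaled units (SD, n = 3 animals, limma adjusted p 0.0048), and row 2643, at 3.03 ± 1.02 (limma adjusted p 0.0067). The lowest were those of row 1102, at -4.39 ± 2.48 (limma adjusted p 0.000801), and row 2376, at -3.23 ± 1.80 (limma adjusted p 0.0069). These rows had the same sign in 3 of 3 animals. The duplicate of row 1102, row 1101, was at 0.14 and had no such effect. The duplicate had the same sign for 9 of the 11 rows and an unadjusted p under 0.05 for 8, and was itself past the threshold for 2. These 2 are rows 1441 and 1442, which are duplicates of each other, so 1 pair enters each of these counts as 2 rows. The calls depended on animal 2: 0 rows passed without it, 18 without animal 1 and 17 without animal 3. The means of animals 1 and 3 kept their sign in 11 of the 11 rows, at sizes of 1.96 to 3.79 scaled units. Those animals helped to select the rows, so the kept sign is no separate support for the calls. The count also depended on the processing: 0 passed with rows of 1 listed symbol averaged, as first planned, whether the arrays were scaled or the values taken as deposited, and 2 passed, both negative, in a joint fit of 12 arrays with a dye term. With odd and even rows averaged, 19 of 1944 pairs passed, 12 of them positive.

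**Figure D3:**
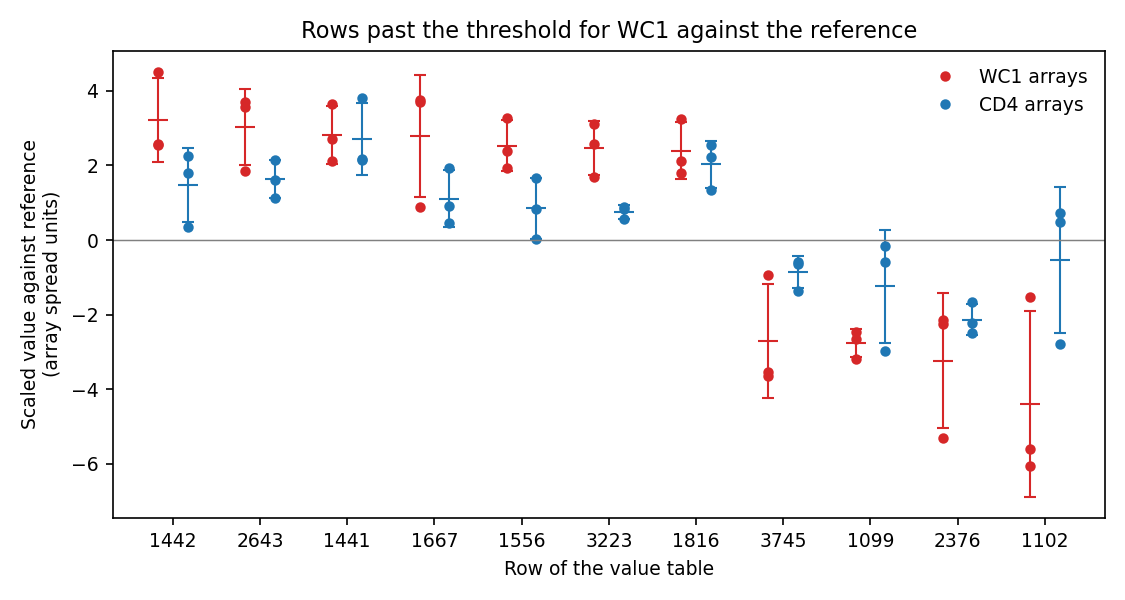
Scaled values against the reference (vertical axis, units of array spread) of the 11 rows past the threshold for WC1, on the 3 WC1 and the 3 CD4 arrays; points are single animals, and bars give the mean and SD. The CD4 mean has the sign of the WC1 mean in 11 of 11 rows, and both share 1 reference pool and dye orientation.

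In these rows the CD4 mean had the sign of the WC1 mean in 11 of 11, all 3 CD4 arrays had it in 10, and the unadjusted CD4 p was under 0.05 in 6. Among the averaged pairs, 3 passed in both populations with the same sign in both. The 6 pairs called in CD4 had the same sign in WC1, as did 18 of the 19 called in WC1 in the CD4 mean. Both populations were compared with the same pool in the same dye orientation, which gives such agreement without any change in the cells; the counts that this alone would give were not computed, so these counts do not show that the populations resembled each other. Rows 1441/1442 averaged 2.09 ± 0.12 in CD4 (SD, n = 3, limma adjusted p 0.037) and 3.02 ± 0.93 in WC1 (limma adjusted p 0.00059). Rows 2375/2376 averaged -2.29 ± 0.15 in CD4 (limma adjusted p 0.027) and -2.85 ± 2.34 in WC1 (limma adjusted p 0.013).

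Across rows, the CD4 and WC1 effects against the reference correlated at a Pearson r of 0.288 (Spearman 0.240, jackknife SE 0.073). Without animals 1, 2 and 3 in turn, r was 0.151, 0.234 and 0.276. All are lower, so the jackknife SE does not measure the full error of r. The CD4 and WC1 effects share 1 reference pool and 1 dye orientation, which creates correlation without any change in the cells. In 100 simulated data sets with unchanged populations, the correlation was 0.501 on average when the pool varied like single arrays and 0.119 when it varied by the part that duplicate spots share. The covariance was 0.132 as measured, and 0.320 and 0.043 in these simulations. The measured value lay between the simulated ones, so a shared response was not separable from the shared reference. With the dye effect estimated from the direct arrays subtracted, the correlation was 0.451 and the covariance 0.266. The same estimate is subtracted from both populations, so its error is common to both and adds to their covariance by construction. The estimate is the average of the swapped arrays as deposited, so it is a dye effect only if the table keeps the dye orientation. On arrays already turned by the authors it would hold the CD4 and WC1 difference.

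The difference between CD4 and WC1 through the reference measured the contrast of the direct arrays on other hybridisations of the same cells. By limma, 0 of 3876 rows passed the threshold (smallest adjusted p 0.331), and 197 rows (5.08%) had an unadjusted p under 0.05 against 193.8 expected by chance. With animal as a replicate block the count was 0 and the smallest adjusted p 0.867. On simulated data this comparison recovered 25.4% of the rows changed by 2 scaled units and 93.9% of those changed by 4, so differences of 2 units would mostly have been missed. The direct and indirect estimates correlated across rows at a Pearson r of -0.046 (Spearman -0.045, jackknife SE 0.0080), and 101 of the 228 rows with an unadjusted p under 0.05 in the direct comparison (44.3%) had the same sign in the indirect one. With the values as deposited this correlation was 0.016, and with the swapped arrays taken as already turned 0.087. The r of -0.046 became -0.027, -0.020 and -0.034 without animals 1, 2 and 3 in turn. All are smaller in size, so the jackknife SE does not measure the full error of this r either. Across duplicate rows the direct and indirect estimates correlated at 0.0018 (bootstrap interval over rows -0.035 to 0.039), so no negative correlation was seen there.

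Of the 26 gene lists fixed for this study, 9 had 0 listed members, 11 had 1 or 2, and 6 had 3 or 4. Averaged over the rows listed under a symbol, 0 of the 37 listed members passed the threshold in any of the 4 comparisons, and 0 lists had a member passing when adjusted over the list alone. Over all listed symbols the counts were 0 as well. The averaged symbols were fitted together with the rows that have no single symbol, and their variance was drawn towards that of the whole set. MAP2K7 in WC1 against the reference, at -0.64 ± 0.04, thus had a limma unadjusted p of 0.167. The counts of 0 therefore do not exclude differences that were steady over animals. A single member had an unadjusted p under 0.05, BOLA-DMA of the MHC class II list in CD4 against the reference, at 1.13 ± 0.12 scaled units (SD, n = 3, limma adjusted p 0.459). Its rows include row 1816, whose duplicate is listed under another gene. In the same comparison BOLA-DRA was at 0.76, with an SD over the animals above its mean, and BOLA-DMB was at -0.06 ± 0.58. In WC1 against the reference CASP4 was at 0.91 ± 0.15, BIRC3 at -0.40 ± 0.15 and TRAF1 at -0.12 ± 0.61, from the apoptosis list. Also in WC1, NFKB1 was at -0.46 ± 0.17, RELA at 0.40 ± 0.24, NFKBIE at -0.08 ± 0.38 and IRAK4 at -0.38 ± 0.36. Of the MAP kinase list, JUN was at 0.06 ± 0.49 there, MAP2K7 at -0.64 ± 0.04, RAC1 at -0.04 ± 1.02 and CDC42 at 0.36 ± 0.64. Of the metabolism list, PKM was at 0.09 ± 0.31, PGK1 at -0.20 ± 0.47 and SLC7A5 at 0.42 ± 0.63. RPLP1 was at -0.41 ± 0.36, RPL13A at -0.16 ± 0.17 and RPSA at -0.46 ± 0.84. The control gene GAPDH, the only gene of the fixed single-gene set that the annotation lists, was at -0.21 ± 0.61 in the direct comparison, -0.12 ± 0.78 in CD4 and -0.10 ± 0.58 in WC1. These symbols are the annotation's, and of the rows listed under 1 accession, those outside an odd and even pair did not behave as replicates, so the values cannot be taken as those of the genes.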

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

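Averaging adjacent rows, removing the trend and taking the swapped arrays as already turned were chosen only after the data were seen. The design as first written (values as deposited with rows of 1 symbol averaged) was the plan, and became a variant after the data were seen. The other alternatives were planned. Without 1 animal in turn, the count of rows past the threshold ranged from 2 to 3 in the direct comparison, from 2 to 65 in CD4 against the reference (65 without animal 3), from 0 to 18 in WC1 against the reference (0 without animal 2) and from 0 to 1 through the reference. The correlation of the direct and indirect estimates then ranged from -0.034 to -0.020, and that of CD4 and WC1 from 0.151 (without animal 1) to 0.276.

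For WC1 against the reference, where 11 rows passed, 7 passed with centring alone, 0 with rows of 1 symbol averaged and 0 in the design as first written. With adjacent rows averaged 19 pairs passed, with the robust prior 18 rows, in the joint fit 2 and with the dye effect subtracted 52. The fit with the dye effect subtracted leaves out the error of the dye estimate and assumes that the values keep the dye orientation. For CD4 against the reference, where 0 passed, 6 pairs passed with adjacent rows averaged and 1 row with the dye effect subtracted. For the direct arrays, where 0 passed, 4 pairs passed with adjacent rows averaged, 1 with the WC1 in Cy3 arrays alone, 3 with a dye term over 6 arrays, 4 with rows of opposite signs left out and 3 with the swapped arrays taken as already turned. The joint fit holds a single CD4 and WC1 contrast over the direct and reference arrays, in which 1 row passed. Through the reference, the paired fit with animal as replicate block left 0. Leaving out rows of opposite signs keeps those whose orientations give the same sign, so the tested effect itself selects them, beside the lower number tested. The other causes were not tested.

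The correlation of the direct and indirect estimates, -0.046, was 0.016 with the values as deposited, which centring alone cannot change. It was 0.020 in the design as first written and 0.087 with the swapped arrays taken as already turned. Without scaling, the arrays with the wide spread weigh most in the direct estimate. The same correlation was -0.060 with rows of 1 symbol averaged and -0.037 with adjacent rows averaged. The correlation of CD4 and WC1, 0.288, was 0.409 with adjacent rows averaged, 0.207 with the trend removed and 0.451 with the dye effect subtracted, where the error of the estimate is common to both by construction. The planned list tests had no list large enough and gave no values. Signal over background is unknown here.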

Other observations

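All tests of explanations in this part were chosen only after the related results were seen.

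The agreement of odd rows with the following even rows was a pattern that no label describes. Neighbours listed under 1 accession outside such a pair correlated at 0.0485, and rows of 1 accession 2 rows apart at 0.092, below the 0.388 inside a pair, which argues against the platform annotation naming these rows. All even and odd neighbours correlated at 0.0807 on the mean of 6 reference arrays, against 0.386 for odd and even rows, which argues against a local mark on the slides as the whole cause. Duplicate spots on odd and even rows remain a candidate explanation. The odd and even correlation was the higher on 12 of 12 arrays, but that is the pattern itself and does not test its cause. No biological explanation was tested, as the design gives none for row order.

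The sum of the swapped arrays agreed between animals better than their difference. A trend shared along the rows was not the whole cause, since the correlation between animals was 0.104 after its removal and 0.155 before. A dye effect of equal strength on every scaled array and a difference between CD4 and WC1 on arrays already turned by the authors stay open and could not be separated. Across duplicate rows the sum correlated with CD4 minus WC1 through the reference at 0.0692 (95% interval over rows 0.024 to 0.116). With the trend removed this was 0.0474 (0.015 to 0.082). The difference of the swapped arrays gave 0.0018 (-0.035 to 0.039), and 0.0010 (-0.035 to 0.038) with the trend removed. The 0.0692 of the sum was not steady over animals. With the reference arrays of animals 1, 2 and 3 taken singly it was 0.081, 0.078 and -0.029. Without animals 1, 2 and 3 in turn it was 0.014, 0.035 and 0.106. The sum also correlated with the mean of the reference arrays, which all carry Cy3 on the T cells, at 0.184 (95% interval over rows 0.119 to 0.248), and at 0.0936 (0.055 to 0.133) with the trend removed.

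The wide spread of 3 direct arrays was not a difference between animals, since the 2 arrays of animal 2, which hold the same RNA, differed 11.96-fold in spread. Duplicate rows on the wide arrays correlated at 0.112 at the least, so noise alone is not the cause. Their highest duplicate correlation, 0.171, lay within the range of the other arrays, so another unit or factor in the deposited values may be the cause. No biological explanation was tested beyond the animals.

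In the comparison of CD4 with WC1 through the reference, the real grouping gave 0 rows and the highest of the other splits 1, so that 10 of the 10 splits gave at least as many; with a real count of 0 this outcome was fixed beforehand and tests nothing. For WC1 against the reference, the real signs gave 11 rows and the highest of the other sign turns 1. Of the 4 sign turns, 1 gave as many, the real one; 4 are too few for a share under 0.05.

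As values without an explanation, the mean of both populations per animal against the reference had 53 of 3876 single rows past the threshold by limma, 43 positive and 10 negative. With odd and even rows averaged, 34 of 1932 pairs passed, 29 of them positive, and 42 passed with the trend removed. Without animal 2 the count was 0, without animal 1 it was 43 and without animal 3 it was 38. The shared reference and dye orientation enter these counts in full.

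On simulated data with 2 CD4 arrays, 0 unchanged rows were called and 40.3% of the rows changed by 2 scaled units were recovered. The recovered share was 55.2% with 3 arrays. This test was added after the 65 rows without animal 3 had been seen. Its noise was independent between rows and arrays, so it cannot tell whether a shared reference, dye effect or trend gave those 65 rows.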
